A study of Mus musculus with 2 samples.

How the data were processed

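RNA was measured by 10x Genomics 3' v3 single-cell sequencing in CD45+ cells sorted from digested and strained subcutaneous MC38 tumours, in 1 library per group (UEIS LSL and UEIS KI). The labels do not say whether mice were pooled. The deposited matrices hold UMI counts per gene and barcode, which the authors made with Cell Ranger and did not normalise. The submitters' notes name Cell Ranger 2.1.1 and mm10, while the file header names Cell Ranger 8.0.1. The annotation was not stated, and 52081 of 55357 gene identifiers (94.1%) matched GENCODE vM21 on GRCm38, the source of the coordinates. No gene symbol in the matrices could be identified as UEIS, so its own RNA was not measured. Barcodes had been filtered before deposit, with lowest totals of 501 and 500 UMIs in UEIS LSL and UEIS KI.

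Barcodes with at least 500 UMIs, at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which left 9370 and 9442. The mitochondrial limit removed 157 and 288. Doublets were the barcodes with the highest Scrublet scores of each library, 0.8% per 1000 barcodes, or 726 and 758, of which 723 and 757 had passed the quality limits, which left 8647 and 8685 cells with median depths of 7903 and 8642 UMIs. Both libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with Leiden resolution 1. Interferon lists, cell cycle genes and receptor variable segments were left out of the clustering genes.

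Clusters were named from 22 fixed marker sets, by the highest mean log2 ratio of a set's markers over all other cells (pseudocount 10 CPM). The limits of this naming were set after the data were seen and over several versions. A name needed a mean of at least 1.5 and at least 3 markers that were each seen in at least 20% of the cluster's cells with a log2 ratio of at least 1. Clusters that met no other set and showed at least 8 of 12 macrophage markers were called macrophage, and the rest of these unnamed myeloid. This limit counted detection alone, and fibroblast-like subclusters 11 and 13 also showed 10 of the 12. The mean log2 ratio of macrophage markers over all other cells was as low as -1.11, in macrophage cluster 12. Clusters of other classes, and those with *Ptprc* in under 40% of cells, were pooled and clustered again on 1500 genes at resolution 2. A name was withheld where more of a group's 10 leading genes were markers of another class, or where its depth was low and none of them was its own marker. A pooled group of these whose C1q level was at least 0.25 of that in macrophages was set apart as a class with macrophage RNA, so this call is made per group and not per barcode. That macrophage level was taken while cluster 15, later called unnamed myeloid, still counted as macrophage. T cells with little macrophage RNA were clustered once more on 15 components for subsets, and no subset was named CD4 T cell. Names describe resemblance, and no protein was measured.

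No test was made, since each group held 1 library and cells are not replicates. Shares are given with exact Clopper-Pearson 95% intervals. For expression, UMI counts were summed per library and class in the 4 classes with at least 100 cells in each library, and scaled to the class total (CPM) with exact Poisson intervals. Ratios are UEIS KI over UEIS LSL with exact conditional binomial intervals, and a count of 0 was set to a floor of 3 counts. All intervals cover counting error only. A gene was measured in a class with at least 50 UMIs over both libraries.

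23 gene lists were fixed before the data were examined, along with the markers, the quality limits and 41 alternatives: type I interferon-induced, interferon-gamma-induced, cGAS-STING pathway, interferon, MHC class I, MHC class II, cytotoxic, exhaustion, naive and memory, regulatory T cell, chemokine, inflammatory myeloid, alternatively activated and tumour-associated macrophage, lysosome and lipid, neutrophil activation, dendritic cell costimulation, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, dissociation stress, unfolded protein response, sex-linked genes and the CD45 gene. Each list is given as the median log2 ratio of its measured members with an interval from 2000 Poisson draws, and the members at least 1.5-fold higher or lower with the counting interval on that side of 1. The symbols Tcrg-C1, Tcrg-C2, Cd163l1, Pyhin1, Mb21d1, Tmem173, Cd39 and Ero1l were missing from the matrices.

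Named genes were chosen by a fixed rule. They needed at least 50 UMIs, a pooled level of at least 50 CPM and an interval excluding 1, and were ranked by the interval bound nearest 1. Up to 10 of the highest and 10 of the lowest were named in the 3 classes with the most cells and the 3 highest and 3 lowest in T cells. Predicted genes, mitochondrial and ribosomal protein genes, haemoglobins, receptor segments, sex-linked genes, and genes under 0.25 of their level in the class with most were left out of the ranking. List examples were the members with the highest counts and the largest ratios.

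On simulated data 2-fold differences were recovered in 95.3% of genes in macrophages, 93.8% in monocytes, 95.4% in cDC2 and 91.4% in T cells, and 1.5-fold differences in 92.5%, 82.3%, 71.9% and 59.6%. The simulated counts were Poisson draws from the pooled profile of each class, without variation between cells, clusters or libraries. Recovery meant an interval excluding 1 on the right side, so these rates describe counting error only. Alternatives changed doublet removal, quality limits, clustering, scaling (edgeR's TMM, DESeq2's size factors, other totals), cell depth, cell weights, cluster mix, free RNA and the UMI minimum of a gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.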

Results

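CD45+ cells sorted from subcutaneous MC38 tumours were profiled by droplet-based 3' single-cell RNA sequencing. MC38 is a mouse colon adenocarcinoma line, and it was grown in C57BL/6 mice named UEIS LSL and UEIS KI, names that the labels do not expand. Each group held 1 library, with 9527 cell barcodes and 92764697 UMIs (unique molecular identifiers) for UEIS LSL and 9734 barcodes and 99404988 UMIs for UEIS KI. The median barcode carried 8117 UMIs and 2577 genes in UEIS LSL and 8759.5 UMIs and 2722 genes in UEIS KI. After quality limits and doublet removal 8647 and 8685 cells remained. There were no replicates, so no difference was tested, and every 95% interval here covers counting error only, not the variation between mice. Ratios are UEIS KI over UEIS LSL, and cell classes are named for the markers they resemble.

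The series title presents UEIS as a micropeptide that dampens cGAS-STING and type I interferon signalling, so the first question was how the immune cells of both libraries were composed. Macrophage-like cells took nearly the same share in both, 76.6% (75.7 to 77.5) of cells in UEIS LSL and 76.8% (75.9 to 77.7) in UEIS KI (exact Clopper-Pearson intervals). Monocyte-like cells took a larger share in UEIS KI, with 5.85% (5.37 to 6.37) in UEIS LSL and 7.40% (6.86 to 7.97) in UEIS KI, a log2 ratio of 0.34 (0.17 to 0.51). Cells resembling cDC2, a dendritic cell type that primes CD4 T cells, took a smaller share in UEIS KI, with 3.44% (3.06 to 3.84) in UEIS LSL and 2.61% (2.29 to 2.97) in UEIS KI, a log2 ratio of -0.39 (-0.65 to -0.14). Neutrophil-like cells numbered 7 and 49 in UEIS LSL and UEIS KI when they carried little macrophage RNA, and with those that also carried macrophage RNA their share was 0.740% (0.570 to 0.944) in UEIS LSL and 2.29% (1.99 to 2.63) in UEIS KI.

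T cell-like barcodes were of 2 kinds, told apart by the macrophage RNA of whole groups of barcodes. Those with little macrophage RNA made up 1.16% (0.942 to 1.41) of cells in UEIS LSL and 1.52% (1.27 to 1.80) in UEIS KI. Those that also carried macrophage RNA made up 2.96% (2.61 to 3.34) and 0.875% (0.690 to 1.09), a log2 ratio of -1.76 (-2.15 to -1.38). Counted together, T cell-like barcodes took 4.12% (3.71 to 4.56) in UEIS LSL and 2.40% (2.08 to 2.74) in UEIS KI, so the direction of the T cell share turned from 0.39 to -0.78 on the log2 scale. With called doublets kept the ratio of the barcodes with macrophage RNA was -1.01. The 100 and 132 T cell-like barcodes with little macrophage RNA held 18 (11.0 to 26.9%) and 36 (19.9 to 35.7%) gamma-delta T cells and 22 (14.3 to 31.4%) and 25 (12.6 to 26.7%) CD8 T cells, with the exact interval of the share in parentheses. The CD8 name rested on 3 markers, and *Cd8a* was seen in 23.4% and *Trdc* in 10.6% of the cells so named. Regulatory T cells numbered 26 (17.7 to 35.7%) and 32 (17.2 to 32.5%), and unnamed T cells 34 (24.8 to 44.2%) and 39 (21.9 to 38.1%). The intervals of the log2 ratio of all 4 subset shares included 0, so no difference was detectable in these barcodes at this depth. T cell-like barcodes with macrophage RNA were not divided into subsets, so the subset shares leave them out. Each of their subclusters held fewer cells in UEIS KI. Subcluster 21, with *Ifng*, *Cd8a* and *Cd8b1* among its leading genes, held 33 in UEIS LSL and 7 in UEIS KI. Subcluster 10, with *Foxp3*, held 68 and 16, subcluster 3 held 114 and 44, and subcluster 20 held 41 and 9. Subcluster 20 had a C1q level of 2258.8 CPM, just above the limit. It would fall below a limit drawn from the final macrophage class, without cluster 15. T cells with little macrophage RNA would then no longer be more numerous in UEIS KI.

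Smaller classes were unequal as well. Mature dendritic cells numbered 90 and 54 in UEIS LSL and UEIS KI, a log2 ratio of -0.74 (-1.26 to -0.24), and cDC1-like cells, which cross-present antigen to CD8 T cells, 26 and 8, at -1.71 (-3.06 to -0.52). B cells numbered 30 and 63, at 1.06 (0.42 to 1.74), and group 2 innate lymphoid cells 5 and 28, at 2.48 (1.09 to 4.21). Fibroblast-like cells numbered 105 and 35, at -1.59 (-2.19 to -1.03). Mast cells numbered 6 and 7, and NK cell-like barcodes, which as a group were called with macrophage RNA, numbered 36 and 36. No group of cells was named as plasmacytoid dendritic cell, plasma cell, basophil, epithelial, endothelial or erythroid cell. The unnamed subcluster 17, with 29 and 28 cells, did have the plasmacytoid genes *Siglech*, *Ccr9*, *Ly6d* and *Klk1* among its 10 leading genes, and stayed unnamed because these outnumbered the markers of the class it scored highest for. When each library was clustered on its own the log2 ratio of the share was 2.25 for monocytes, 4.39 for B cells, 5.10 for neutrophils with little macrophage RNA, 0.084 instead of 1.39 for those with macrophage RNA, -3.74 for the NK cell-like barcodes and 0.20 for fibroblasts. The neutrophil ratio of 2.80 was 1.46 at the higher cluster resolution.

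**Figure D1:**
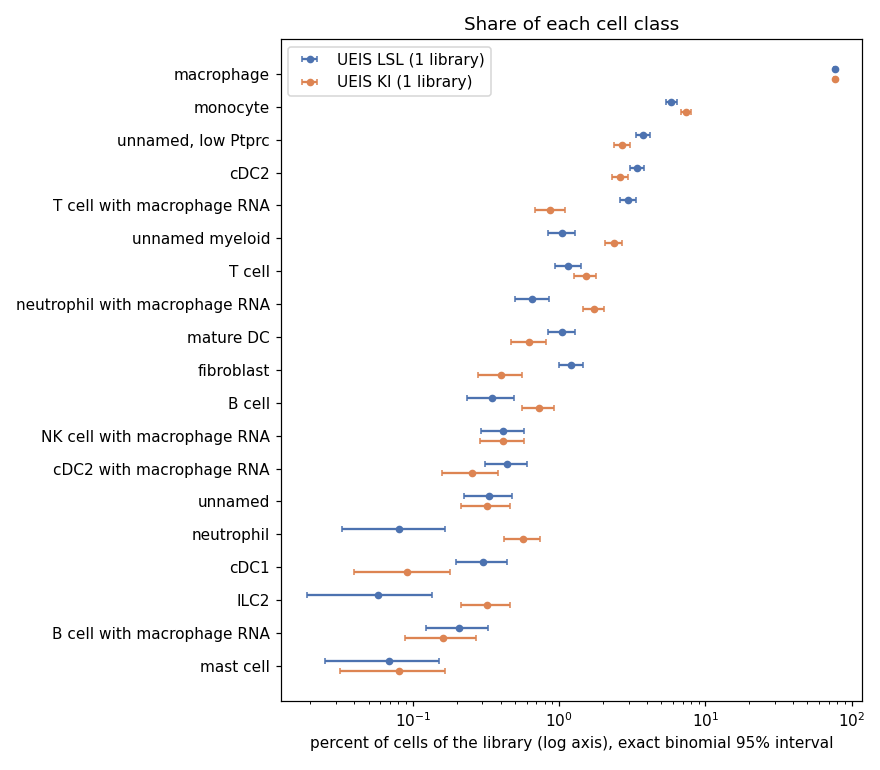
Share of each cell class in percent of the cells of its library, on a log axis, with exact binomial 95% intervals, for 1 library per group. Macrophage-like cells sit at 76.6% and 76.8%, while T cell-like barcodes with macrophage RNA sit at 2.96% in UEIS LSL and 0.875% in UEIS KI.

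The second question, set by the series title, was how interferon-induced RNA compared between the libraries in each cell class. Genes on the type I interferon list were lower in UEIS KI in all 4 classes that held at least 100 cells in each library. No test separated a response to type I interferon from one to interferon-gamma. The median log2 ratio of the type I list was -0.87 (-0.94 to -0.83) in macrophages, -0.73 (-0.86 to -0.63) in monocytes, -0.91 (-1.11 to -0.78) in cDC2 and -0.57 (-0.77 to -0.30) in T cells. Of the measured members, 40 of 52 in macrophages, 27 of 37 in monocytes, 25 of 39 in cDC2 and 3 of 7 in T cells were at least 1.5-fold lower in UEIS KI, and 0 in any of these classes were at least 1.5-fold higher. Among them, *Ifitm3*, a membrane protein that blocks virus entry, went from 1222 to 708 CPM in macrophages, and *Ifi213* from 10.4 to 2.54. *Rsad2*, the antiviral enzyme viperin, went from 32.1 to 11.0 in monocytes and from 107 to 22.2 in cDC2, and *Usp18*, a brake on interferon receptor signalling, from 24.6 to 4.87 in cDC2. In T cells *Bst2*, which tethers budding virus, went from 179 to 90.8. The T cell median rests on 7 genes in barcodes where free RNA was estimated at 29.3% of the median depth in UEIS LSL and 17.9% in UEIS KI. It is therefore not free of RNA from the other classes.

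Genes induced by interferon-gamma gave a median of -1.14 (-1.20 to -1.08) in macrophages, with 0 higher, 20 lower and 3 neither of 23 by the 1.5-fold limit, and -1.004 (-1.13 to -0.75) in monocytes, with 0 higher, 11 lower and 3 neither. In cDC2 the median was -0.45 (-0.83 to -0.40), with 0 higher, 7 lower and 9 neither, and in T cells -0.20 (-0.66 to 0.11), with 0 higher, 1 lower and 4 neither, and 0.29 for the same genes in T cell subcluster 7 alone, where only 2 of them were measured, at a median of 0.37. *Cxcl9*, a chemokine that draws activated T cells, went from 149 to 24.8 CPM in macrophages and from 47.1 to 7.84 in monocytes, and *Cxcl10*, another ligand of the same receptor, from 246 to 114 in macrophages. The components of the cGAS-STING pathway themselves had medians near 0, at -0.040 (-0.093 to 0.0024) in macrophages, 0.0022 (-0.14 to 0.10) in monocytes and -0.019 (-0.18 to 0.13) in cDC2, and 0.44 (0.089 to 0.76) over 4 genes in T cells. In macrophages 2 of 19 were at least 1.5-fold higher and 0 lower. *Enpp1*, which degrades the messenger that cGAS makes, went from 11.6 to 22.7 in macrophages, and *Cgas*, the DNA sensor, from 19.1 to 7.55 in monocytes.

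After every cell was thinned to 1000 UMIs, *Isg15*, an interferon-induced ubiquitin-like protein, was seen in 8.86% (8.19 to 9.58) of UEIS LSL macrophages and 3.27% (2.86 to 3.73) of UEIS KI macrophages. In cDC2 these shares were 15.3% (11.4 to 19.9) and 5.29% (2.76 to 9.05). *Cxcl9* was seen in 4.46% (3.97 to 4.99) and 1.18% (0.931 to 1.47) of macrophages, whose median depths were 7894 and 9278.5 UMIs. In T cells, which should lack *Cxcl9*, it was seen in 1 of 90 in UEIS LSL and in 0 of 120 in UEIS KI, which allows up to 3.03%, so these T cells were too few to set a background for *Cxcl9*. Their median depths were 1790.5 and 1788 UMIs. Within UEIS KI macrophages *Cxcl9* ran from 1.79 CPM in cluster 7 to 540.0 CPM in cluster 18. Macrophages held 4.95 UMIs of the type I list per thinned cell in UEIS LSL and 3.28 in UEIS KI.

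The macrophage value depended on which clusters were weighed. Over the 13 macrophage clusters with at least 30 cells in each library, the type I median ran from -1.83 in cluster 3 to 0.22 in cluster 9. The *Isg15* log2 ratio, in cells not thinned, ran from -2.27 in cluster 3 to 1.17 in cluster 9. Its interval lay above 0 in clusters 2, 8, 9, 12 and 18, and below 0 in clusters 0, 1, 3, 4, 5, 7, 11 and 16. The clusters were unevenly filled, with cluster 0 holding 424 and 1278 cells and cluster 2 holding 1213 and 300. With both libraries weighted to the same mix of clusters the macrophage medians were -0.50 for the type I list and -0.53 for the interferon-gamma list, with *Ifi213* at -1.22 and *Cxcl10* at -0.31 instead of -2.03 and -1.11. In monocytes *Rsad2* was at -0.61 and *Cxcl9* at -1.27 with the looser mitochondrial limit, instead of -1.54 and -2.59, and *Cgas* at -2.33 in thinned cells instead of -1.34. In cDC2 the type I median was -0.45 when cells needed at least 500 detected genes, and in T cells it was -0.25 when every cell counted alike and -0.28 with called doublets kept. T cell subcluster 7 was the only one with at least 30 cells in each library (54 and 65), so the settings on the mix of clusters describe that subcluster alone in T cells. Its type I median was -0.27 over the 5 genes measured in it.

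**Figure D2:**
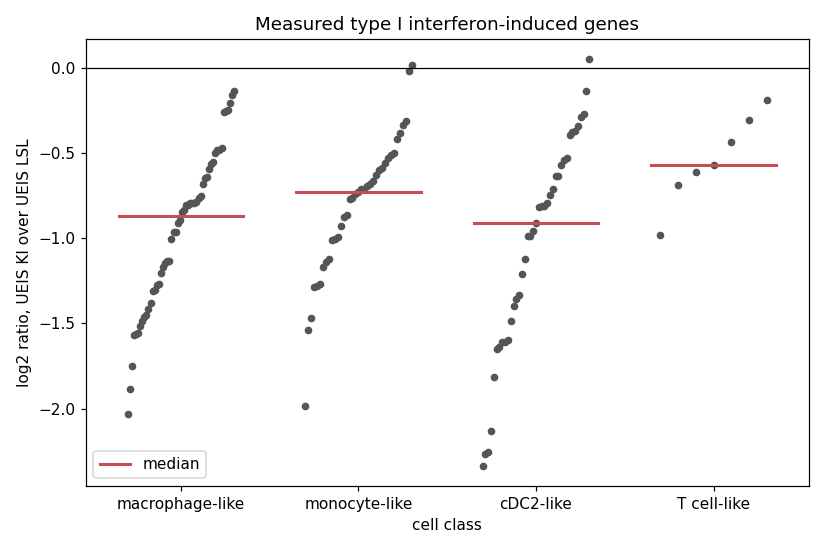
Log2 ratio (UEIS KI over UEIS LSL) of each measured gene of the type I interferon list, 1 point per gene, in each of the 4 cell classes, with the median as a line. The medians sit at -0.87 in macrophages, -0.73 in monocytes, -0.91 in cDC2 and -0.57 in T cells.

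Interferon transcripts themselves were scarce, and their values by class were chosen after they were seen. *Ifng*, the interferon-gamma gene (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892 of GRCm38), gave 740 UMIs over all UEIS LSL cells and 88 over all UEIS KI cells, or 9.19 and 1.02 CPM, a log2 ratio of -3.18 (-3.51 to -2.86). T cell-like barcodes with macrophage RNA held 550 and 22 of these UMIs, 74.3% and 25.0% of the gene's total. Within that class *Ifng* went from 163 to 25.9 CPM, in T cells with little macrophage RNA from 209 to 90.8 CPM and in NK cell-like barcodes from 466 to 147 CPM. T cell RNA differed too, since the barcodes with macrophage RNA held 13.2 and 7.91 UMIs of 5 T cell receptor genes per barcode, and those with little of it 10.8 and 8.24. *Cd3e*, 1 of these 5, went from 13.5 to 5.47 CPM over all cells, so these *Ifng* values in CPM are not levels per T cell. *Ifnb1*, the interferon-beta gene, gave 96 and 31 UMIs over all cells, a log2 ratio of -1.73 (-2.37 to -1.14), and macrophages held 58 and 21 of these UMIs. The macrophage log2 ratio of *Ifnb1* was -1.71, but -0.092 when every cell counted alike, -0.14 as a mean within clusters and -0.76 with the same mix of clusters. In cDC2 *Ifnb1* went from 9.17 to 2.71 CPM on 25 and 5 UMIs, in cDC2 with macrophage RNA the other way, with 0 and 5 UMIs, and the unnamed subcluster 17 gave 5 and 0. *Ifnl3* gave 2 and 0 UMIs, and the other 8 interferon genes of the list, *Ifna1*, *Ifna2*, *Ifna4*, *Ifna5*, *Ifna6*, *Ifna12*, *Ifne* and *Ifnl2*, gave 0 in both libraries.

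**Figure D3:**
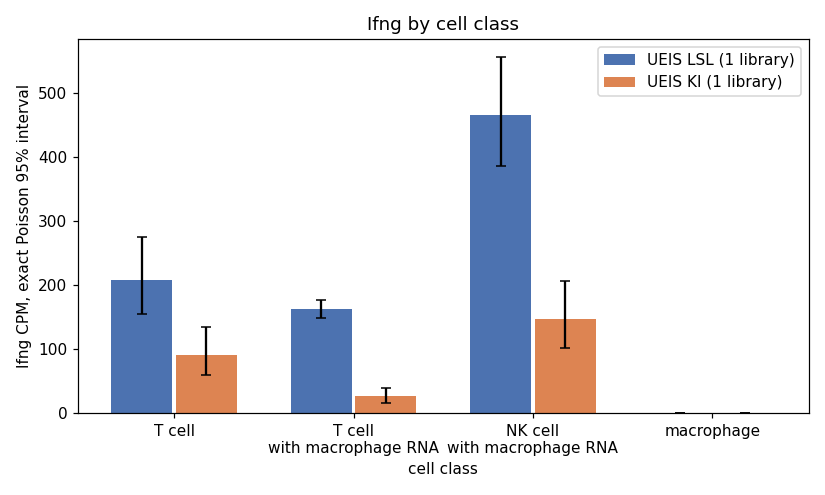
*Ifng* in CPM of each cell class, as bars from 0 with exact Poisson 95% intervals, for 1 library per group. T cell-like barcodes with macrophage RNA sit at 163 CPM in UEIS LSL and 25.9 CPM in UEIS KI.

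In macrophages *Lyz1* ranked first among the higher genes and *Cxcl9* first among the lower ones. *Lyz1*, a lysozyme gene (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868), was 14.990-fold (95% counting interval 14.3 to 15.7) higher in UEIS KI, at 30.3 to 454 CPM, and its neighbour *Lyz2*, the main lysozyme of myeloid cells (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), was lower, from 9172 to 6193 CPM. *Spp1*, which encodes osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), was 2.73-fold (95% counting interval 2.71 to 2.74) higher, from 3055 to 8337 CPM. *Lyve1*, *Folr2* and *Fcna*, genes of tissue-resident macrophages, were 3.55-fold, 1.90-fold and 3.31-fold higher. The cell division genes *Ube2c* and *Cdca3* were 2.03-fold and 1.85-fold higher, and *Pmp22*, *Sh3bp5* and *Serpinb6a* 2.16-fold, 2.03-fold and 1.98-fold higher. *Cxcl9* (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) was 6.02-fold (95% counting interval 5.71 to 6.34) lower, and *Tmem176b* 3.23-fold, the Fc receptor gene *Fcgr4* 2.60-fold, *Lst1* 2.15-fold and the neutrophil chemokine gene *Cxcl3* 2.07-fold lower. The lectin receptor genes *Clec4a1* and *Clec4a3* were each 2.02-fold lower, *Ly86*, a partner of a Toll-like receptor relative, 1.89-fold, the heat shock gene *Hspa1a* 1.80-fold and the interferon-induced *Ifi204* 1.80-fold. With the same mix of clusters the log2 ratios were -1.31 for *Cxcl9* instead of -2.59, 0.73 for *Lyve1* instead of 1.83, 0.89 for *Fcna* instead of 1.73 and 0.21 for *Folr2* instead of 0.93. As a mean within clusters *Lyz1* was at 4.86 instead of 3.91.

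Antigen presentation genes were lower in UEIS KI macrophages. MHC class II genes had a median of -1.10 (-1.31 to -1.07), with 0 higher, 10 lower and 3 neither of 13. *Cd74*, the invariant chain that guides class II assembly (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), went from 10845 to 2861 CPM, *H2-Eb1* from 1929.9 to 414 and *Ciita*, the master regulator of class II genes, from 18.7 to 3.54. The *Cd74* level in macrophages was 0.156 of that in the class with the highest level, which was cDC2. MHC class I genes had a median of -0.52 (-0.57 to -0.50), with 0 higher, 9 lower and 14 neither, among them *H2-D1* from 1733 to 1219, *B2m* from 1598 to 1161 and *H2-Q7* from 44.6 to 16.2. The class II median was -0.65 with the same mix of clusters, where *Cd74*, *H2-Eb1* and *Ciita* were at -1.10, -1.27 and -1.50 on the log2 scale, and it was negative in each of the 13 clusters.

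Cell cycle genes were higher in UEIS KI macrophages, with a median of 0.45 (0.41 to 0.49) and 14 higher, 0 lower and 16 neither of 30, such as *Stmn1* from 362 to 457 and *Cenpf* from 26.4 to 54.5. With the same mix of clusters this median was 0.052. Alternatively activated and tumour-associated macrophage genes had a median of 0.11 (0.092 to 0.13), with 8 higher, 1 lower and 20 neither. Beside *Spp1*, *Lyve1* and *Folr2* it held *Apoe*, a lipid carrier, from 3929 to 3713. Inflammatory myeloid genes had a median of -0.19 (-0.28 to -0.16), with 1 higher, 2 lower and 18 neither, among them *Il1b* from 1418 to 893 and *Marco*, a scavenger receptor gene, from 3.20 to 6.11. When every cell was thinned the inflammatory list turned to 0.0036 and *Apoe* to 0.25, and the direction of *Marco* turned with the same mix of clusters, to -0.27. Chemokines had a median of -0.31 (-0.39 to -0.29), with 1 higher, 7 lower and 13 neither. *Cxcl2* went from 3280.3 to 2501 and *Pf4* from 1826 to 2045. Dendritic cell costimulation and migration genes had -0.49 (-0.54 to -0.36), with 0 higher, 5 lower and 11 neither, and -0.21 with the same mix of clusters. Unfolded protein response genes had -0.40 (-0.43 to -0.33), with 0 higher, 5 lower and 11 neither, such as the chaperone gene *Hspa5* from 919 to 606, and dissociation and immediate-early stress genes -0.23 (-0.25 to -0.20), with 0 higher, 2 lower and 23 neither, such as *Fos* from 4914 to 3926.

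Lists that held near 0 in macrophages were lysosome and lipid handling genes, at 0.013 with 0 higher, 0 lower and 21 neither (-0.015 with TMM and -0.020 with median-of-ratios scaling), and neutrophil activation and maturation genes, at -0.020 with 4 higher, 2 lower and 20 neither. *Psap* went from 3152 to 2532, *Ctsd* from 1014 to 1346 and *Fth1*, an iron storage gene, from 15819.7 to 17048. Glycolysis and hypoxia genes had 0.10 with 1 higher, 0 lower and 28 neither, such as *Gapdh* from 5015 to 5541 and *Ankrd37* from 66.9 to 96.1, and oxidative phosphorylation genes 0.12 with 0 higher, 0 lower and 24 neither, such as *Cox4i1* from 1093 to 1250.4 and *Atp5e* from 924 to 882. The glycolysis median was -0.046 with thinned cells. Lymphocyte lists were also read in macrophages. Their members *Ccl5* and *Klrk1* stood at 0.003 and 0.014 of their level in the class with most. The cytotoxic list had -0.39 with 0 higher, 4 lower and 6 neither, the exhaustion list 0.21 with 2 higher, 1 lower and 11 neither, the naive and memory list -0.18 with 2 higher, 2 lower and 9 neither, and the regulatory T cell list -0.28 with 0 higher, 3 lower and 5 neither. With thinned cells the regulatory T cell list turned to 0.23, and after subtraction of free RNA measured from C1q the naive and memory list turned to 0.14. *Ptprc*, the gene of the CD45 sort marker, went from 217 to 192. *Xist* stood at 562 and 569 CPM over all cells, while the Y-linked genes gave 1 UMI in UEIS LSL and 0 in UEIS KI. The sex-linked list had -0.27 over 2 genes.

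**Figure D4:**
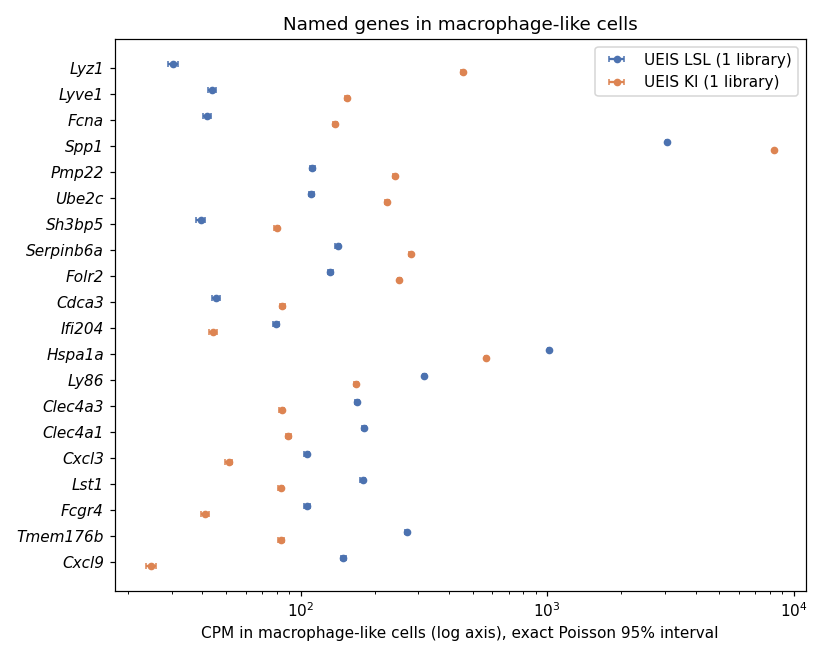
The 20 genes named by rank in macrophage-like cells, in CPM of the class total on a log axis, with exact Poisson 95% intervals, for 1 library per group. *Lyz1* sits at 30.3 CPM in UEIS LSL and 454 CPM in UEIS KI, and *Cxcl9* at 149 and 24.8 CPM.

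Monocytes shared the *Lyz1* difference, 15.2-fold (95% counting interval 11.5 to 20.6) higher in UEIS KI, and their *Lyz2* was 1.99-fold (95% counting interval 1.96 to 2.03) lower. *Chil3*, a chitinase-like protein of classical monocytes, was 2.11-fold higher, and *Hopx*, *Ltc4s*, which makes leukotriene C4, *Vcan* and *Ecm1* were 2.34-fold, 2.32-fold, 2.08-fold and 2.02-fold higher. *Plec*, *Atp2b4*, *Spp1* and *Lmna* were 1.99-fold, 2.14-fold, 1.74-fold and 1.75-fold higher. The interferon regulatory genes *Irf7* and *Irf1* were 2.25-fold and 2.05-fold lower, the chemokine gene *Ccl12* 1.97-fold, *H2-DMb1*, which loads class II molecules, 1.89-fold, and *Tmem176b*, *Fcrls*, *Ms4a4c*, *Mndal* and *Ly86* 2.14-fold, 2.07-fold, 1.90-fold, 1.996-fold and 1.79-fold lower. MHC class II genes had a median of -0.92 (-1.004 to -0.79), with 0 higher, 8 lower and 3 neither, such as *Cd74* from 11218 to 5903 and *H2-Aa* from 3115 to 1396 CPM. MHC class I genes had -0.47 (-0.53 to -0.41), with 0 higher, 7 lower and 14 neither, chemokines -0.37 (-0.45 to -0.24), with 0 higher, 5 lower and 13 neither, and cell cycle genes -0.34 (-0.56 to -0.23), with 0 higher, 6 lower and 12 neither. Alternatively activated genes had 0.080 (0.025 to 0.18), with 7 higher, 2 lower and 20 neither, among them *Fn1*, fibronectin, from 2249 to 3715. Neutrophil activation genes had 0.18 (0.13 to 0.22), with 5 higher, 2 lower and 15 neither, such as *Lcn2* from 8.53 to 35.4, at 0.007 of its highest class level and a thinned log2 ratio of 1.13 instead of 2.05, in the library where *S100a8*, a neutrophil marker chosen after its values were seen, stood at 185 CPM over all cells against 26.2. Medians of the other lists in monocytes, single-gene lists included, ran from -0.24 for unfolded protein response genes to 0.21 for exhaustion and checkpoint genes.

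In cDC2, *Rsad2* was 4.81-fold (95% counting interval 3.46 to 6.85) lower in UEIS KI, *Gbp2*, a guanylate-binding protein of cell-autonomous immunity, 3.02-fold and *Cxcl9* 2.81-fold. *Ms4a4c*, *Ifi209*, *Ifi27l2a*, *Ear2*, the lectin gene *Cd209a* and the Fc receptor gene *Fcgr1* were 2.41-fold, 2.18-fold, 1.76-fold, 2.08-fold, 1.94-fold and 1.93-fold lower. Among higher genes, *Pdlim7* was 1.77-fold, *Dapk1* 1.76-fold, *Foxn3* 1.61-fold, *Plec* 1.59-fold, *Tamalin* 1.56-fold and *Cirbp* 1.51-fold higher, and *Rgs2*, *Mpc1*, *Klf4* and *Clec4n* 1.47-fold, 1.36-fold, 1.34-fold and 1.34-fold. MHC class II genes were close to equal in cDC2, at -0.059 (-0.13 to -0.017) with 0 higher, 0 lower and 13 neither, *Cd74* going from 41908 to 41541 and *H2-Aa* from 12219 to 12211 CPM. MHC class I genes had -0.43 (-0.54 to -0.39), with 0 higher, 7 lower and 15 neither, and dendritic cell costimulation and migration genes -0.0006 (-0.21 to 0.17), with 1 higher, 2 lower and 11 neither. The regulatory T cell list had 0.53 (0.18 to 0.77) over 5 genes, led by *Tnfrsf9*, a costimulatory receptor, from 43.3 to 109. Inflammatory myeloid genes had -0.26 (-0.43 to -0.094), with 0 higher, 3 lower and 12 neither, and unfolded protein response genes -0.32 (-0.39 to -0.18), with 0 higher, 2 lower and 11 neither. The CD45 gene was at -0.19. Medians of the other lists in cDC2 that had at least 3 measured genes lay between -0.11 for lysosome genes and 0.15 for neutrophil activation genes, which turned to -0.14 in thinned cells, and cell cycle genes, at 0.11, turned to -0.19 with the same mix of the 2 cDC2 subclusters large enough to weigh. In thinned cells the log2 ratios were -3.43 for *Rsad2* instead of -2.27 and 1.65 for *Dapk1* instead of 0.81. With at least 500 detected genes they were -1.59 for *Rsad2*, -0.52 for *Ifi209* and -1.09 for *Usp18*, and *Tnfrsf9* was at 0.51 as a mean within clusters.

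In T cells with little macrophage RNA *Scart2* and *Il17a*, genes of interleukin 17-making gamma-delta T cells, ranked first among the higher genes. *Scart2*, a scavenger receptor of these cells, was 10.8-fold (95% counting interval 5.03 to 27.7) higher in UEIS KI, and *Il17a* 3.43-fold (95% counting interval 2.62 to 4.54) higher in the library with 36 gamma-delta T cells against 18. *Rrad* was 2.85-fold higher. *Rgs16*, a regulator of G protein signalling, was 3.50-fold lower, *Hspa1b* 1.99-fold lower and *AW112010*, an interferon-inducible transcript, lower from 2032 to 1016 CPM. Cytotoxic and effector genes had a median of -0.62 (-0.77 to -0.17), with 1 higher, 4 lower and 8 neither of 13, but members went both ways. *Ifng* was lower and *Gzmb*, a granzyme that kills target cells, went from 225 to 523 CPM. *Gzmb* was among the 10 leading genes of the regulatory T cell subset and not of the CD8 T cell subset. It is also in the regulatory T cell list, so its rise is not a measure of CD8 T cell killing. Naive and memory genes had 0.48 (0.20 to 0.76) over 6 genes, with *Tcf7*, a transcription factor of memory-like T cells, from 70.9 to 178 and *Satb1* from 179 to 305. Exhaustion and checkpoint genes had 0.043 (-0.17 to 0.28), with 2 higher, 1 lower and 5 neither, such as *Ctla4* from 655 to 729.6, and regulatory T cell genes 0.065 (-0.11 to 0.19), with 1 higher, 0 lower and 11 neither. In T cell subcluster 7 alone the log2 ratios were -0.081 for *Rgs16* instead of -1.81, 0.26 for *Gzmb* instead of 1.21 and 1.04 for *Ctla4* instead of 0.16. *Scart2* was at 2.35 or 1.45 there instead of 3.43, and *Il17a* at 6.42 or 5.29 instead of 1.78, depending on how the value added to each count was scaled. Thinned cells of all T cell subclusters gave 2.0 for *Scart2* and 1.40 for *Il17a*. In subcluster 7 the exhaustion list was at 0.79 and the regulatory T cell list at 0.65, over the genes measured in the whole class. The other 2 subclusters, 1 of them with *Il17a* and *Scart2* among its leading genes, were too small for such a value. Free RNA was estimated at 29.3% and 17.9% of the median T cell depth. Tumour-associated macrophage genes had -0.44 in these barcodes but 0.31 when every cell counted alike, chemokines -0.47 but 0.26, and MHC class II genes -0.21 but 4.10 after subtraction of free RNA measured from C1q. A sum emptied by that subtraction was set to the floor, so the 4.10 is not read as a difference in level. Medians of the other lists in T cells that had at least 5 measured genes lay between -0.21 for lysosome genes, which turned to 0.034 when every cell counted alike, and 0.16 for neutrophil activation genes.

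**Figure D5:**
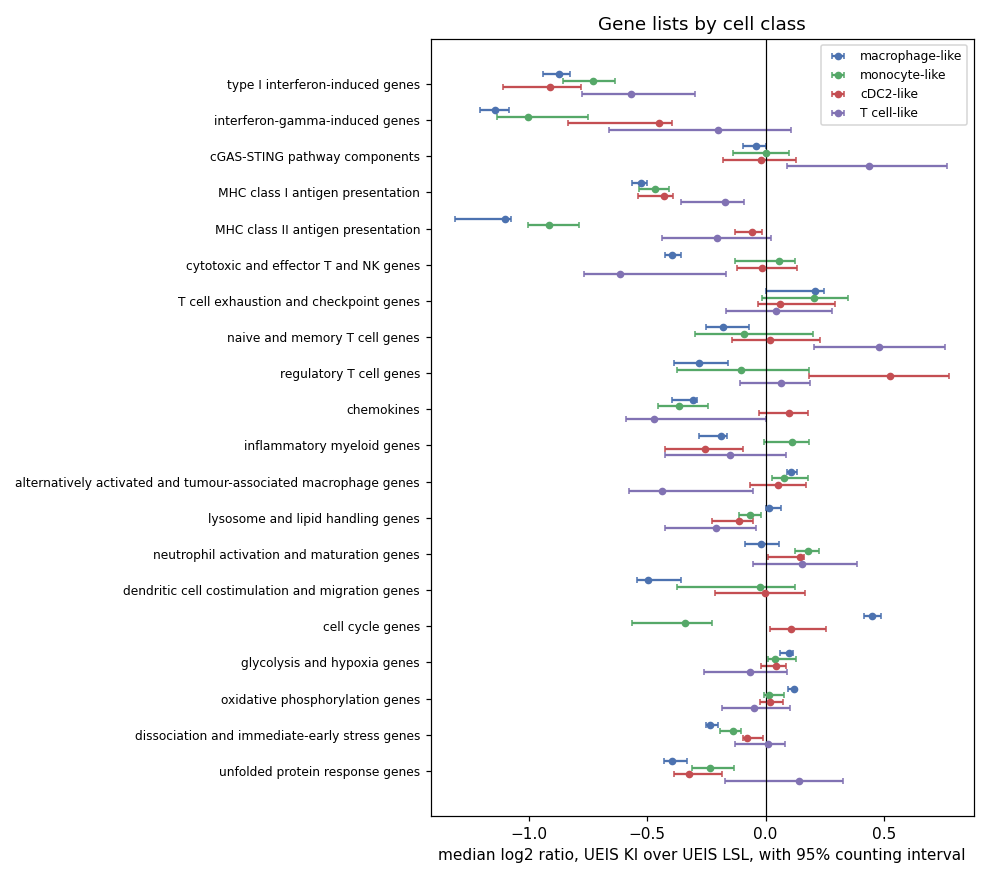
Median log2 ratio (UEIS KI over UEIS LSL) of each gene list in each of the 4 cell classes, with 95% counting intervals. MHC class II genes sit at -1.10 in macrophages and -0.059 in cDC2, and cell cycle genes at 0.45 in macrophages and -0.34 in monocytes.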

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

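The tests on free RNA in macrophages, whose bound was set before its value was computed, on the mix of clusters, on reads shared between the lysozyme genes and all 3 on barcodes with macrophage RNA were chosen only after the result was seen. The hypothesis of a lost *Lyz2* copy came from *Lyz2* values already seen. Differences between classes in the direction of a list were not tested, since each group held 1 library. Of the lists with at least 3 measured genes, 4 had counting intervals on opposite sides of 0 in a pair of classes and both medians in the outer tails of random lists. They lay 0.66 apart on the log2 scale for naive and memory genes between T cells and macrophages, and 0.81 apart for regulatory T cell genes between cDC2 and macrophages. They lay 0.55 apart for alternatively activated and tumour-associated macrophage genes between macrophages and T cells, and 0.79 apart for cell cycle genes between macrophages and monocytes. Some alternatives removed or narrowed these contrasts. Naive and memory genes in macrophages were at 0.061 as a mean within clusters, and regulatory T cell genes there at 0.23 in thinned cells. Tumour-associated macrophage genes in T cells were at 0.31 when every cell counted alike. Cell cycle genes were at 0.052 in macrophages with the same mix of clusters and at -0.047 in monocytes when every cell counted alike.

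Several values lie outside the comparisons of named classes and stand above what a count of 0 allows. An unnamed myeloid group took 1.04% of cells in UEIS LSL and 2.36% in UEIS KI, and an unnamed group low in *Ptprc* 3.75% and 2.72%. Other unnamed cells took 0.335% and 0.322%, and barcodes of any class with macrophage RNA 4.68% and 3.43%. Barcodes over the mitochondrial limit made up 1.65% and 2.96% of all barcodes. *Hbb-bs*, a haemoglobin gene, stood at 3.19 and 27.5 CPM over all cells.

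The lower interferon-induced RNA in UEIS KI macrophages was first set against depth and scaling. The median nearest 0 over 4 scalings was -0.88, and after subtraction of free RNA it was -0.87, values that argue against both as the whole of it. With the same mix of clusters the median was -0.50 instead of -0.87. The mix of these clusters may thus account for part of the difference but not for all of it. A different mix of cells inside a cluster would not be removed by this weighting and stays open. Interferon-gamma-induced genes and *Ifng* itself were lower too, so these values cannot tell which interferon the type I list reflects. The UEIS genotype, a difference between the mice or tumours and a difference between the library preparations stay open and untested, since each group held 1 library.

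*Lyz2* was lower and *Lyz1* higher in UEIS KI. Reads shared between these paralogs would leave their sum equal, but its log2 ratio in monocytes was -0.93, and the loss of *Lyz2* UMIs per cell was 7.66 times as large in macrophages as in T cells, which argues against free RNA. For a strain segment, 21 measured genes within 2 Mb of *Lyz2* were read, with *Lyz1* left out. Their median absolute log2 ratio lay at percentile 54.2 of random lists. A strain segment need not change the RNA level of the genes in it, so this value cannot decide on it. As a hypothesis, 1 of 2 *Lyz2* copies may not be read in UEIS KI, as in mice with a Cre inserted in *Lyz2*, which the labels do not mention. In 64.3% of clusters, between the bounds set for and against it, the *Lyz2* ratio was near that of a lost copy. The *Lyz2* ratios of all clusters ran from -1.21 to -0.27, so for *Lyz2* a lost copy and another regulation cannot be told apart. A lost *Lyz2* copy does not by itself predict the rise of *Lyz1*, whose log2 ratio ran from 1.67 to 8.85 over the same clusters. The highest value, in cluster 18, rests on a *Lyz1* level of only 1.67 CPM in 157 UEIS LSL cells, with an interval of 6.98 to 11.9. The UEIS genotype itself stays open and untested.

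T cell-like barcodes with macrophage RNA were 6.67 times as many as chance doublets would give in UEIS LSL before doublet removal. Chance doublets at the assumed rate thus do not account for them all. Their median depth exceeded that of other T cell-like barcodes by at least 17.6 times the free RNA of a droplet. The limit of this comparison was set after its value was seen. That free RNA was estimated from C1q in T cell-like groups kept for their low C1q, which holds the estimate down. The comparison therefore cannot decide on free RNA. The C1q level of the barcodes with macrophage RNA was not used directly, since it defines the class. Their ratio to barcodes without macrophage RNA was at least 2.59 times as high for T cell-like as for B cell-like barcodes. T cells captured together with macrophages or taken up by them would give such an excess, but it was not particular to T cells. Neutrophil-like barcodes with macrophage RNA, 57 in UEIS LSL and 150 in UEIS KI, also outnumbered the 7 and 49 without. All NK cell-like barcodes, 36 and 36, were called with it. The contrast with B cells therefore cannot decide on such pairs. Whether the UEIS genotype lies behind their lower share in UEIS KI was not tested.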

How the results depend on the processing

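Tests chosen only after the data were seen were those with barcodes that carry macrophage RNA counted in their class, free RNA measured from C1q, the same mix of clusters, the richest cluster left out and cluster 15 counted as macrophage, and all alternatives for the shares of classes with macrophage RNA and for *Ifng* and *Ifnb1* over all cells. No paired analysis was possible because each group held 1 library. Of the values under an alternative, 730 medians of lists stayed within their counting interval, 119 moved beyond it and 20 reversed, a word kept for medians whose interval excluded 0. The sign also changed in 20 of those that moved and 43 of those that stayed, all with intervals that included 0. For shares the first 3 counts were 109, 13 and 3, and for single genes 3663, 876 and 50, with 1 and 7 further changes of sign among shares and 65 and 91 among genes. Alternatives on clustering were run for shares alone, and of the lists only the type I list was run with other quality limits or with doublets kept. All 8 values of *Ifng* and *Ifnb1* over all cells stayed within theirs. The type I median was below 0 in all 4 classes under every alternative run. Intervals are narrow where a class holds many UMIs, as in macrophages, and wide in T cells, where the depth limits what can be seen. No value was obtained for NK cell-like barcodes at Leiden resolution 0.5 or with the looser mitochondrial limit, for cDC1 with either quality alternative, for cDC1, ILC2 and mast cells with each library clustered on its own, or for some lists of T cells, cDC2 and monocytes with at least 200 UMIs per gene. T cell subsets were computed with 1 setting. The 2 settings on the mix of clusters use clusters with at least 30 cells in each library. Monocytes were 1 cluster, so their medians could hardly move there, yet they are counted above. In T cells both settings describe subcluster 7 alone (54 and 65 cells), where the value added to each count weighs on genes of few UMIs, and in cDC2 they use 2 subclusters. Each pair of values that follows is a log2 ratio as reported and then under the alternative, and the cause was not tested.

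With called doublets kept, and equally with Scrublet's automatic threshold, which called 0, the log2 ratio of the share of T cell with macrophage RNA went from -1.76 to -1.01. In cDC2, *Ccr7* went from 0.70 to -0.11, *Fth1* from 0.15 to -0.0003 and *Gapdh* from 0.082 to -0.012. In T cells, type I genes went from -0.57 to -0.28.

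With at most 20% mitochondrial UMIs, the log2 ratio of the share of macrophage went from 0.0034 to -0.047 and neutrophil from 2.80 to 1.48. In cDC2, *Ccr7* went from 0.70 to -0.67. In T cells, *Ifitm3* went from -0.61 to 0.12.

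With at least 500 detected genes, *Ccl6* went from 0.072 to -0.11 in monocytes. In cDC2, type I genes went from -0.91 to -0.45 and *Hmox1* from -1.17 to 0.36.

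At Leiden resolution 0.5, the log2 ratio of the share of neutrophil went from 2.80 to 1.46.

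At Leiden resolution 2, the log2 ratio of the share of neutrophil went from 2.80 to 1.46.

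With each library clustered on its own, the log2 ratio of the share of monocyte went from 0.34 to 2.25, fibroblast from -1.59 to 0.20, B cell from 1.06 to 4.39, neutrophil from 2.80 to 5.10 and neutrophil with macrophage RNA from 1.39 to 0.084. That of NK cell with macrophage RNA went from -0.0063 to -3.74, cDC2 with macrophage RNA from -0.79 to 1.58 and B cell with macrophage RNA from -0.37 to -4.04.

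With barcodes that carry macrophage RNA counted in their class, the log2 ratio of the share of T cell went from 0.39 to -0.78 and neutrophil from 2.80 to 1.63.

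With TMM scaling, tumour macrophage genes went from 0.11 to 0.079, lysosome genes from 0.013 to -0.015, oxidative genes from 0.12 to 0.091 and stress genes from -0.23 to -0.26 in macrophages. In cDC2, oxidative genes went from 0.019 to -0.036 and stress genes from -0.077 to -0.13.

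With DESeq2's size factors, cytotoxic genes went from -0.39 to -0.43, tumour macrophage genes from 0.11 to 0.073, lysosome genes from 0.013 to -0.020, oxidative genes from 0.12 to 0.086 and stress genes from -0.23 to -0.27 in macrophages. In macrophages, unfolded protein genes went from -0.40 to -0.43. In cDC2, oxidative genes went from 0.019 to -0.028 and stress genes from -0.077 to -0.12.

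With every cell thinned to 1000 UMIs, cGAS-STING genes went from -0.040 to 0.015, MHC class I from -0.52 to -0.47, MHC class II from -1.10 to -0.999, cytotoxic genes from -0.39 to -0.20 and exhaustion genes from 0.21 to 0.35 in macrophages. In macrophages, naive and memory genes went from -0.18 to -0.42, regulatory T genes from -0.28 to 0.23, chemokines from -0.31 to -0.21, inflammatory genes from -0.19 to 0.0036 and tumour macrophage genes from 0.11 to 0.25. In macrophages, dendritic genes went from -0.49 to -0.26, cell cycle genes from 0.45 to 0.40, glycolysis genes from 0.10 to -0.046, oxidative genes from 0.12 to 0.070 and stress genes from -0.23 to -0.12. In macrophages, *Igfbp4* went from -0.13 to 0.039, *Il27* from -0.61 to 0.997, *Apoe* from -0.082 to 0.25 and *Xist* from -0.055 to 0.023. In monocytes, type I genes went from -0.73 to -0.89, MHC class I from -0.47 to -0.39, naive and memory genes from -0.089 to -0.43, regulatory T genes from -0.10 to 0.25 and tumour macrophage genes from 0.080 to 0.32. In monocytes, glycolysis genes went from 0.041 to 0.20, stress genes from -0.14 to -0.20, *Prdm1* from 0.57 to -0.0081, *Ccl6* from 0.072 to -0.057 and *Tk1* from -1.57 to 0.085. In cDC2, MHC class I went from -0.43 to -0.37, exhaustion genes from 0.059 to -0.18, regulatory T genes from 0.53 to 0.15, chemokines from 0.10 to 0.37 and inflammatory genes from -0.26 to -0.018. In cDC2, tumour macrophage genes went from 0.051 to -0.15, neutrophil genes from 0.15 to -0.14, dendritic genes from -0.0006 to 0.21, unfolded protein genes from -0.32 to -0.44 and *Gbp3* from -1.44 to 0.051. In cDC2, *Nfkb1* went from 0.28 to -0.0054, *Enpp1* from 0.85 to -0.85, *Klrd1* from 0.27 to -0.11, *Tnfrsf18* from 0.56 to -0.14 and *Stmn1* from 0.24 to -0.072. In cDC2, *Mcm3* went from 0.56 to -0.26, *Higd1a* from 0.40 to -0.28 and *Ptprc* from -0.19 to 0.094. In T cells, cGAS-STING genes went from 0.44 to 0.056, MHC class II from -0.21 to 0.045, chemokines from -0.47 to 0.078, tumour macrophage genes from -0.44 to 0.19 and *Ifitm3* from -0.61 to 0.17. In T cells, *Apoe* went from -0.51 to 0.19 and *Arg1* from -0.81 to 0.85.

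With every cell counted alike, MHC class I went from -0.52 to -0.44, MHC class II from -1.10 to -0.98, cytotoxic genes from -0.39 to -0.26, regulatory T genes from -0.28 to 0.12 and chemokines from -0.31 to -0.27 in macrophages. In macrophages, inflammatory genes went from -0.19 to -0.072, tumour macrophage genes from 0.11 to 0.25, dendritic genes from -0.49 to -0.30, glycolysis genes from 0.10 to 0.00 and oxidative genes from 0.12 to 0.072. In macrophages, stress genes went from -0.23 to -0.10, *Igfbp4* from -0.13 to 0.021, *Apoe* from -0.082 to 0.25 and *Xist* from -0.055 to 0.089. In monocytes, type I genes went from -0.73 to -0.86, chemokines from -0.37 to -0.18, cell cycle genes from -0.34 to -0.047, glycolysis genes from 0.041 to 0.21 and *Ccl6* from 0.072 to -0.091. In cDC2, neutrophil genes went from 0.15 to 0.18. In T cells, type I genes went from -0.57 to -0.25, chemokines from -0.47 to 0.26, tumour macrophage genes from -0.44 to 0.31, lysosome genes from -0.21 to 0.034 and *Apoe* from -0.51 to 0.043. In T cells, *Arg1* went from -0.81 to 0.64 and *Fth1* from -0.12 to 0.070.

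As a mean within clusters, type I genes went from -0.87 to -0.49, interferon-gamma genes from -1.14 to -0.57, MHC class I from -0.52 to -0.38, MHC class II from -1.10 to -0.63 and cytotoxic genes from -0.39 to -0.25 in macrophages. In macrophages, naive and memory genes went from -0.18 to 0.061, regulatory T genes from -0.28 to -0.39, chemokines from -0.31 to -0.25, inflammatory genes from -0.19 to -0.025 and lysosome genes from 0.013 to -0.013. In macrophages, neutrophil genes went from -0.020 to 0.11, dendritic genes from -0.49 to -0.18, cell cycle genes from 0.45 to 0.22, glycolysis genes from 0.10 to 0.18 and oxidative genes from 0.12 to 0.068. In macrophages, stress genes went from -0.23 to -0.14, unfolded protein genes from -0.40 to -0.26, *Bhlhe40* from -0.070 to 0.13, *Marco* from 0.93 to -0.025 and *Chac1* from -0.73 to 0.034. In cDC2, type I genes went from -0.91 to -0.68, tumour macrophage genes from 0.051 to 0.35, cell cycle genes from 0.11 to -0.056, glycolysis genes from 0.044 to 0.094 and *Hmox1* from -1.17 to 0.27. In T cells (subcluster 7 alone), interferon-gamma genes went from -0.20 to 0.29, exhaustion genes from 0.043 to 0.77, regulatory T genes from 0.065 to 0.64, tumour macrophage genes from -0.44 to 0.29 and oxidative genes from -0.050 to -0.27.

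With the same mix of clusters, type I genes went from -0.87 to -0.50, interferon-gamma genes from -1.14 to -0.53, MHC class I from -0.52 to -0.41, MHC class II from -1.10 to -0.65 and cytotoxic genes from -0.39 to -0.18 in macrophages. In macrophages, chemokines went from -0.31 to -0.26, inflammatory genes from -0.19 to -0.11, tumour macrophage genes from 0.11 to 0.066, lysosome genes from 0.013 to -0.026 and neutrophil genes from -0.020 to 0.084. In macrophages, dendritic genes went from -0.49 to -0.21, cell cycle genes from 0.45 to 0.052, glycolysis genes from 0.10 to 0.19, oxidative genes from 0.12 to 0.061 and stress genes from -0.23 to -0.13. In macrophages, *Bhlhe40* went from -0.070 to 0.0006 and *Marco* from 0.93 to -0.27. In cDC2, type I genes went from -0.91 to -0.69, tumour macrophage genes from 0.051 to 0.41, cell cycle genes from 0.11 to -0.19, glycolysis genes from 0.044 to 0.14 and *Hmox1* from -1.17 to 0.47. In cDC2, *Stmn1* went from 0.24 to -0.029. In T cells (subcluster 7 alone), interferon-gamma genes went from -0.20 to 0.29, exhaustion genes from 0.043 to 0.79, regulatory T genes from 0.065 to 0.65, tumour macrophage genes from -0.44 to 0.30 and oxidative genes from -0.050 to -0.27.

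With 5% of the summed profile subtracted, regulatory T genes went from -0.28 to -0.11, dendritic genes from -0.49 to -0.31 and *Tnfrsf4* from -1.12 to 0.018 in macrophages. In monocytes, *Ctsk* went from 2.40 to -0.23.

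With free RNA measured from C1q subtracted, naive and memory genes went from -0.18 to 0.14, regulatory T genes from -0.28 to 0.029, dendritic genes from -0.49 to -0.27 and *Tnfrsf4* from -1.12 to 1.32 in macrophages. In monocytes, *Ctsk* went from 2.40 to -0.28. In T cells, MHC class II went from -0.21 to 4.10, chemokines from -0.47 to 0.18, neutrophil genes from 0.16 to -0.053, *Spp1* from 0.73 to -0.31 and *Fth1* from -0.12 to 0.092. Sums emptied by this subtraction were set to the floor, so the 4.10 is not read as a difference in level.

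With at least 200 UMIs per gene, MHC class II went from -1.10 to -1.33 and dendritic genes from -0.49 to -0.31 in macrophages. In cDC2, tumour macrophage genes went from 0.051 to -0.071. In T cells, MHC class II went from -0.21 to 0.037 and neutrophil genes from 0.16 to 0.43.

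With at least 20 UMIs per gene, cytotoxic genes went from 0.055 to -0.36 in monocytes. In cDC2, neutrophil genes went from 0.15 to 0.17. In T cells, tumour macrophage genes went from -0.44 to -0.019.

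Without the cluster richest in type I RNA, type I genes went from -0.87 to -0.79 in macrophages.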

Other observations

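An unnamed myeloid group, cluster 15, was rich in protease genes. Its *Acp5*, the acid phosphatase of osteoclasts, stood at 14400.4 CPM, *Ctsk*, a collagen-degrading protease, at 13044 and *Mmp9*, a matrix protease, at 4560.0 over both libraries, and it held 90 cells in UEIS LSL and 205 in UEIS KI. Cluster 12, counted as macrophage with 187 and 304 cells, also had *Acp5* and *Ctsk* among its 10 leading genes. The group low in *Ptprc* carried *Tm4sf1* and *Sox9*, with 324 and 236 cells, and its subclusters had between 2.36 and 35.4 CPM of *Xist*, against 562 and 569 over all cells. These genes were chosen after their values were seen.

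*Hbb-bs* gave 257 UMIs in UEIS LSL and 2376 in UEIS KI, and of the latter 85.9% lay in macrophages and 12.2% in fibroblast-like cells. *Cd3e*, a T cell receptor subunit, stood at 13.5 and 5.47 CPM over all cells. Neutrophils with little macrophage RNA held 16.6% and 39.1% of the *S100a8* UMIs, and those with macrophage RNA 43.7% and 43.0%. These genes, too, were chosen after their values were seen.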
